A study of Mus musculus with 6 samples.

How the data were processed

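Total RNA of progenitor cells sorted by flow cytometry from the bone marrow of C57BL/6JRj mice was extracted with TriZol and made into libraries with a TruSeq RNA kit, per the labels' protocols. The 6 libraries were grouped by the cell type label alone: 3 were labelled CD27 high MODP and 3 were labelled CD27 low MOP. Whether the libraries of a group came from separate animals is not given in the sources used here, so the p-values measure the spread between these libraries, which may be partly technical.

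The deposited table held raw read counts per Ensembl gene, with no normalization, as its whole-number values show. The submitters' processing notes name TopHat 1.4 and HTSeq, without a version for HTSeq. The genome build, the annotation, the strand setting of the counting and the read length are not given in the sources used here, and no coordinates are printed for that reason. Without a known strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart. The table had 22271 genes. Symbols were taken from the GENCODE M21 annotation by gene identifier, which matched 20840 identifiers and left 1431 without a symbol. Those 1431 held 0.816% of all counts, and 367 of them were among the tested genes.

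Library totals ran from 10701425 to 15892640 counts. TMM factors from edgeR lay between 0.983 and 1.03, and the 10 most abundant genes took 4.62% to 6.73% of a library. All values per library are CPM values (counts per 1000000) computed here with TMM-scaled library sizes. Genes were kept by edgeR's filterByExpr, which left 12850 genes for testing. The comparison of MOP with MODP was edgeR's quasi-likelihood test with robust estimation, group as the sole factor and Benjamini-Hochberg adjustment over all tested genes, at a threshold of 0.05. An edgeR adjusted p in the text is this value unless another fit is named beside it. Standard errors of log2 fold changes come from the same fit.

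The 24 gene lists, this test and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists. Counts of members past the threshold are given over all genes tested and, where they differ, adjusted over the list alone. Camera was repeated with the correlation estimated for each list. Of the 17 lists called with the preset correlation, only the early progenitor list was called with the estimated correlation. Fry was also run: its directional test asks whether a list's genes move, on balance, one way, and its mixed test whether they change in either direction; neither compares a list with other genes.

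Named genes followed 3 rules. The first took 8 sort and reference genes, whatever their test said. The second took up to 3 members of each list past the threshold, by smallest adjusted p, or the most abundant member where none passed. The third took the 8 genes with the largest and the 8 with the smallest log2 fold change among genes past the threshold whose groups did not overlap and whose higher group averaged at least 10 CPM. Genes without a symbol or with a near-identical copy were passed over in the third rule. Other list members that are named were chosen after their values were seen. Some genes that these rules take are not reported here.

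To mark genes that share reads with copies, the 31-mers of each gene's longest GENCODE M21 transcript were looked up on both strands in the transcripts of all other genes. Genes with at least 50% of their 31-mers shared were marked as uncertain, which held for 638 tested genes and 134 of those past the threshold. The check bears on that annotation, which may differ from the one the authors used.

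Pairing was checked before any calls were compared. The sample titles number the libraries WT1, WT2 and WT1 in each group, whereas the column names of the deposited count table number them 1, 2 and 3, as the replicates are numbered here. Deviations from the group means were correlated over 9351 genes above a mean log2 CPM of 3. Such deviations cancel out within a group, so high correlations for some pairs push the others down, and the values are not independent. Libraries with the same column number correlated at 0.59, 0.61 and 0.51, and other pairs across the groups at -0.45 to 0.05. The column numbers were therefore taken as pairs, and a fit with the replicate number as a block was added after the data had been seen. It is given beside a result where it changed a call or moved a count by over 1.5 times.

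Within a group, the chi-square statistic of the counts of any 2 libraries was 8.01 to 38.2 per degree of freedom, so no library was a repeat of another within sampling noise. The test was checked on simulated counts for the same 12850 genes and library sizes with 200 genes changed. It recovered 43.8% of 48 tested genes changed 1.5-fold, 70% of 50 changed 2-fold, 96% of 50 changed 4-fold and all 50 changed 8-fold. Of its 163 calls, 9 (5.52%) were false. In a simulation with 1 shifted list, camera found that list and called 0 of the lists that share no gene with it. The simulated genes were drawn independently of each other, so this does not check the preset correlation for genes that vary together.

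Alternatives fixed beforehand were DESeq2's size factors (RLE), upper-quartile scaling, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2, limma-voom, no robust estimation, the title number as a block, a test against a 1.5-fold change (glmTreat) and leaving out each library. The fit without both replicate 2 libraries was added after the data had been seen. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The figures were drawn with matplotlib in Python.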

Results

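Whole transcriptomes were measured in a pair of sorted mouse bone marrow progenitor populations that the labels call CD27-high MODP and CD27-low MOP. CD27 is a cell surface receptor of the TNF receptor family. The series' title speaks of a progenitor of macrophages and osteoclasts that descends from a shared progenitor of these cells and of dendritic cells, and the design compares both populations. Each had 3 libraries. MODP replicates 1, 2 and 3 held 11946538, 10701425 and 13846749 counts, and MOP replicates 1, 2 and 3 held 13833340, 15892640 and 13338577. Between 17941 and 19017 genes had at least 1 read in a library.

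MOP cells differed from MODP cells across much of the transcriptome: stem and early progenitor genes such as Hoxa9, Flt3 and Kit were lower in MOP, and monocyte, macrophage and lysosome genes such as Ccr2, Mpeg1 and Ctsc were higher. Of 12850 genes tested, 2095 were higher in MOP and 1913 were lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At least 2-fold differences were found in 493 of the higher and 385 of the lower genes, and at least 4-fold differences in 116 and 96. The libraries of the groups did not overlap for 6116 genes (47.6% of those tested, against 10% by chance). The first principal component held 60.3% of the variance and separated the groups, and the second held 22.9% and set replicate 2 of each group apart from the other libraries. Without MOP replicate 1 the 4008 genes past the threshold became 2317 (1281 higher and 1036 lower), and without MODP replicate 1 the lower genes became 1264. Under upper-quartile scaling the split became 1692 higher and 2452 lower.

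**Figure D1:**
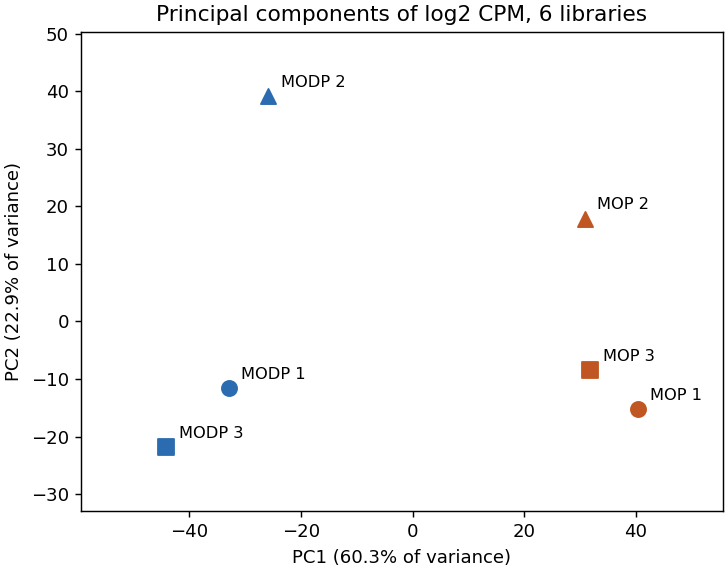
Scores of the 6 libraries on the first and second principal components of log2 CPM, with colour for the group and marker shape for the replicate number. PC1 (60.3% of variance) parts MODP from MOP, and PC2 (22.9%) places replicate 2 of both groups above the others.

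The genes that define the sort and the populations came first. Cd27 (ENSMUSG00000030336), the sort marker, stood at 37.6 ± 1.99 CPM in MODP and 3.91 ± 0.571 CPM in MOP (SD, n = 3), a log2 fold change of -3.27 ± 0.12 (SE) with an edgeR adjusted p of 2.5e-05. Flt3 (ENSMUSG00000042817), a cytokine receptor of dendritic and lymphoid progenitors, was 3.64-fold lower in MOP, at 30.5 ± 3.07 against 111 ± 8.11 CPM (edgeR adjusted p = 4.3e-05). Kit (ENSMUSG00000005672), the stem cell factor receptor, was 2.45-fold lower, at 138 ± 20.7 against 338 ± 33.8 CPM (edgeR adjusted p = 0.00064). Csf1r (ENSMUSG00000024621), the M-CSF receptor on which macrophages and osteoclasts depend, was 1.71-fold higher in MOP, at 514 ± 46.5 against 301 ± 42.1 CPM (edgeR adjusted p = 0.0022). The monocyte genes Ly6c2 and Cx3cr1 were higher by log2 0.60 ± 0.05 and 0.74 ± 0.17 (SE; edgeR adjusted p = 0.00033 and 0.019).

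Tnfrsf11a (ENSMUSG00000026321), which encodes RANK, the receptor for the osteoclast-inducing cytokine RANKL, was low in both populations, at 1.56 ± 0.477 CPM in MODP and 3.34 ± 0.364 CPM in MOP. Its log2 fold change was 1.12 ± 0.28 (SE, edgeR adjusted p = 0.018). Itgam, the integrin CD11b, averaged 226 ± 175 CPM in MODP and 306 ± 106 CPM in MOP, and the difference did not pass the test (edgeR adjusted p = 0.67). It stood at 427 and 428 CPM in replicate 2 of MODP and MOP, and without both of these libraries the edgeR adjusted p was 0.0047, against 0.082 to 1 in the other alternatives. Itgam is also uncertain because 74.1% of its 31-mers occur in other genes. The call for Tnfrsf11a was lost in 4 of the 6 fits without a library, namely without replicate 1 or 3 of MODP or replicate 1 or 2 of MOP (edgeR adjusted p 0.0066 to 0.073 over the 6). That for Cx3cr1 was lost in 3, without MOP replicate 1 or 3 or MODP replicate 3 (edgeR adjusted p 0.011 to 0.082 over the 6).

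**Figure D2:**
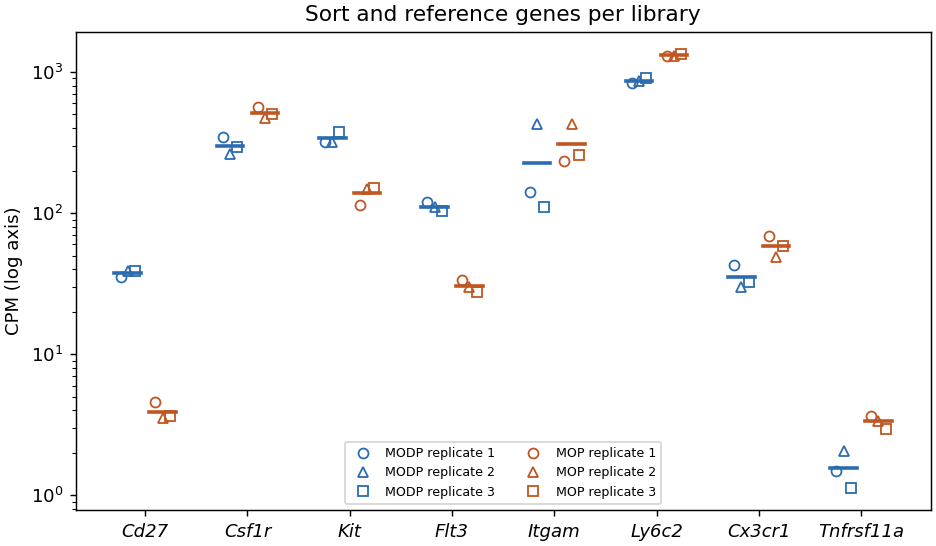
CPM on a log axis of the 8 sort and reference genes in each library, with open symbols for replicates 1, 2 and 3 and bars for the group means. Cd27 falls from a mean of 37.6 to 3.91 CPM, Kit and Flt3 are lower in every MOP library, and Itgam is near 427 CPM in replicate 2 of both groups.

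Genes of stem cells and early progenitors were lower in MOP as a group. Of the 28 tested members of this list, 20 were lower, 5 were higher and 3 did not pass the test; adjusted over the list alone, 20 were lower and 6 were higher. The median log2 fold change was -1.28. Hoxa9, a homeobox factor of stem and progenitor cells, fell from 17.2 ± 1.67 to 2.20 ± 0.882 CPM, and Meis1, its cofactor, from 20.1 ± 1.71 to 6.23 ± 0.429 CPM. Adgrg1, an adhesion receptor of stem cells, fell by 1.28 ± 0.07 (SE) on the log2 scale, Cd34 by 1.11 ± 0.10 and Sox4 by 1.93 ± 0.10, though 54.6% of the 31-mers of Sox4 are shared with other genes. The 5 higher members were the transcription factor genes Runx1, Gata2, Tal1 and Sox6 and the G protein regulator gene Rgs1, with log2 fold changes of 0.48, 2.44, 0.44, 1.23 and 1.72; Gata2 is also on the basophil and mast cell list. The camera adjusted p was 8.4e-17, and adjusted p = 0.045 with an estimated correlation. Gata2 lost its call with the replicate number as a block (edgeR adjusted p = 0.052). CPM summed over the T and NK list was also lower in every MOP library, at 77.2 to 129 against 281 to 392. Most of each sum was 1 gene, Nkg7, at 204 to 240 CPM in MODP and 65.0 to 99.3 CPM in MOP. The sum moved in the same direction as the early progenitor group and as the granulocyte, stromal and endothelial and ribosomal protein groups described below.

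Monocyte and macrophage genes were higher in MOP. Of 42 tested members, 25 were higher, 0 were lower and 17 did not pass, with the same counts adjusted over the list alone and a median log2 fold change of 0.85. Ccr2, the chemokine receptor of classical monocytes, rose by log2 1.47 ± 0.10 (SE), and Mpeg1, a pore-forming protein of macrophages, rose from 363 ± 39.0 to 885 ± 39.6 CPM. Fn1, which encodes fibronectin, rose from 158 ± 74.4 to 1201 ± 213 CPM. S100a4 rose by log2 2.48 ± 0.16 (SE), but 57.5% of its 31-mers are shared with other genes. Lyz2, the lysozyme of macrophages and neutrophils, averaged 862 ± 697 CPM in MODP and 2359 ± 297 CPM in MOP and did not pass the test (edgeR adjusted p = 0.18); MODP replicate 2 was at 1660.3 CPM. By camera, the adjusted p was 3.0e-18, and adjusted p = 0.34 with an estimated correlation. CPM summed over the basophil, mast cell and eosinophil list was also higher in every MOP library, at 3934 to 5699.8 against 760.4 to 1582, and moved in the same direction as the adhesion, innate, MHC class II, osteoclast, lysosome, dendritic cell, cytokine receptor, erythroid and megakaryocyte and cell cycle groups described below.

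Receptors for adhesion, chemokines and microbial products moved the same way. On the chemokine receptor and adhesion list, which shares 11 members with other lists, 10 of 25 members were higher in MOP and 0 were lower, among them Selplg, the ligand of selectins, at log2 0.92 ± 0.10 (SE), and the integrin gene Itgb3 at 0.89 ± 0.10. Camera gave an adjusted p of 7.8e-05, and adjusted p = 0.34 with an estimated correlation. On the innate sensing list 14 of 32 members were higher, 1 was lower and 17 did not pass. The toll-like receptor gene Tlr9 rose by log2 1.19 ± 0.14 (SE) and the inhibitory Fc receptor gene Fcgr2b by 0.37 ± 0.05, and Tlr5 rose from 1.67 ± 0.227 to 4.41 ± 0.138 CPM. The lower member was the lectin gene Clec12a, at log2 -0.30. The camera adjusted p was 0.00019, and adjusted p = 0.54 with an estimated correlation. Without MODP replicate 1, MOP replicate 1 or MOP replicate 2, 7, 8 or 9 members of the innate list were higher, and 3 were lower with the replicate number as a block, against 2 with the title number or without both replicate 2 libraries.

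Of the 11 genes for antigen presentation on MHC class II, 4 were higher in MOP, 0 were lower and 7 did not pass. H2-Oa and H2-DMb1, which act in peptide loading, rose by log2 1.15 ± 0.17 and 0.65 ± 0.08 (SE), and the protease gene Ctss rose from 74.6 ± 19.1 to 179 ± 9.20 CPM. Cd74, the invariant chain, did not pass the test (edgeR adjusted p = 0.53) and stood at 46.6, 159 and 28.0 CPM in MODP replicates 1 to 3 and at 105, 162 and 116 CPM in MOP. By camera, the adjusted p was 0.0048, and adjusted p = 0.52 with an estimated correlation. The count of higher members was 9 without MODP replicate 2, and 9 without replicate 2 of both groups.

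Osteoclast genes were on balance higher in MOP. The list held 36 genes, of which 34 were in the deposited counts and 27 passed the count filter, and it shares 7 members with other lists. Of 27 tested members 13 were higher, 1 was lower and 13 did not pass. Adjusted over the list alone, 16 were higher and 1 was lower. Tfe3, a transcription factor of osteoclasts and lysosomes, rose from 38.2 ± 5.00 to 70.6 ± 2.45 CPM. Itgb3, a subunit of the vitronectin receptor, rose from 32.6 ± 4.73 to 60.2 ± 1.56 CPM, and Tyrobp, an adaptor for activating receptors, rose by log2 0.97 ± 0.12 (SE). Trem2, a partner of Tyrobp, had a log2 fold change of 2.06 and Acp5, the tartrate-resistant acid phosphatase, of 0.96. Nfatc1, the transcription factor that drives osteoclast differentiation, stood at 76.8 ± 8.47 and 85.0 ± 3.66 CPM and did not pass the test (edgeR adjusted p = 0.22). The lower member was the kinase gene Src, at log2 -1.25 (edgeR adjusted p = 0.036). Camera gave an adjusted p of 4.2e-06, and adjusted p = 0.34 with an estimated correlation. The count of lower members was 0 in 5 of the 6 fits without a library, all but that without MODP replicate 1, and 0 with DESeq2, without a filter on low counts and with a filter of 1 CPM in 3 libraries; it was 2 with the replicate number or the title number as a block.

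Lysosome genes followed the same direction. Of 31 members 21 were higher in MOP, 1 was lower and 9 did not pass, and 23 were higher adjusted over the list alone. Ctsc, the protease that activates granule enzymes, rose from 117 ± 3.69 to 295 ± 18.5 CPM, Grn, which encodes progranulin, from 324 ± 23.9 to 573 ± 36.8 CPM, and the membrane protein gene Lamp1 from 475 ± 38.3 to 835 ± 65.1 CPM. The lower member was Gaa, the acid glucosidase gene, at log2 -0.33. The camera adjusted p was 3.6e-09, and adjusted p = 0.34 with an estimated correlation. The count of lower members was 2 with the replicate number or the title number as a block and 0 without replicate 1 or 3 of MODP or replicate 1 or 2 of MOP.

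Dendritic cell genes moved unevenly. Of 28 tested members 8 were higher in MOP, 2 were lower and 18 did not pass, with the same counts adjusted over the list alone. The higher members included Naaa, a lipid hydrolase gene of conventional dendritic cells, which rose from 18.4 ± 3.20 to 98.9 ± 7.05 CPM. Btla, an inhibitory receptor, rose from 11.3 ± 1.27 to 31.1 ± 0.710 CPM, and Zbtb46, a transcription factor of conventional dendritic cells, from 2.70 ± 1.23 to 8.67 ± 0.548 CPM. The lower members were Flt3 and Clnk, at log2 -1.86 and -2.75. Irf8, a factor needed for a subset of conventional dendritic cells, stood at 686 ± 162 CPM in MODP and 995 ± 140 CPM in MOP. It did not pass the test (edgeR adjusted p = 0.088). By camera, the adjusted p was 0.0075, and adjusted p = 0.52 with an estimated correlation. With the replicate number as a block Irf8 was called (edgeR adjusted p = 0.00017).

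On the plasmacytoid dendritic cell list the members split: of 19 tested, 4 were higher in MOP, 6 were lower and 9 did not pass; adjusted over the list alone, 5 were higher and 6 were lower. The lower members included the transcription factor genes Tcf4 and Runx2, which fell by 0.58 ± 0.08 and 0.63 ± 0.09 (SE) on the log2 scale, and Siglech, a surface marker of these cells, which fell from 11.8 ± 4.10 to 4.29 ± 1.22 CPM. Dntt, the terminal transferase of lymphoid progenitors, fell from 41.3 ± 11.1 to 2.52 ± 1.62 CPM. Tlr9 and the receptor gene Lag3 were higher, at log2 1.19 and 2.19. Camera did not call the list (adjusted p = 0.44). Without MODP replicate 1, 2 members were higher.

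Cytokine receptors changed in both directions. Of 26 genes 13 were higher in MOP, 5 were lower and 8 did not pass, and 14 were higher adjusted over the list alone. Csf2ra, a chain of the GM-CSF receptor, rose from 169 ± 16.6 to 327 ± 19.2 CPM. Il1rl1, the IL-33 receptor, rose from 8.60 ± 1.53 to 29.0 ± 4.73 CPM, and Il18r1, the IL-18 receptor, from 9.63 ± 3.56 to 54.6 ± 15.1 CPM; basophils and mast cells can express both, and the sum of their list was higher in every MOP library. The lower members were Flt3, Kit, Il21r, Ifngr1 and Il1r1. Camera gave an adjusted p of 0.0050, and adjusted p = 0.39 with an estimated correlation. On the TNF receptor superfamily list 6 of 19 genes were higher, 1 (Cd27) was lower and 12 did not pass; Tnfrsf14 and Tnfrsf1a rose by log2 0.91 ± 0.12 and 0.28 ± 0.05 (SE), and camera did not call the list (adjusted p = 0.86). The count of higher TNF receptor genes was 3 without MOP replicate 1 or without MODP replicate 3, and 2 genes were lower without MODP replicate 2 and with the replicate number or the title number as a block.

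Granulocyte genes fell in part. Of 24 tested members 6 were lower in MOP, namely Mpo, Elane, Ctsg, Prtn3, Ms4a3 and Gfi1, 0 were higher and 18 did not pass. Mpo, the myeloperoxidase gene, fell from 14760.9 ± 989 to 7850.1 ± 818 CPM, or by 0.91 ± 0.08 (SE) on the log2 scale; Elane and Ctsg, which encode granule proteases, fell by 0.77 ± 0.07 and 0.80 ± 0.08. S100a8, a gene of mature neutrophils, did not pass the test (edgeR adjusted p = 0.89) and was highest in replicate 2 of each group. S100a8 stood at 629.9, 2832 and 411 CPM in MODP replicates 1 to 3 and at 476, 1941 and 849.6 CPM in MOP. The camera adjusted p was 0.030, and adjusted p = 0.72 with an estimated correlation. The camera call was also lost under upper-quartile scaling (adjusted p = 0.073), with the title number as a block (adjusted p = 0.061), without MOP replicate 1 (adjusted p = 0.12) and without MODP replicate 2 (adjusted p = 0.64), where 1 member was higher. Without replicate 2 of both groups it was lost too (camera adjusted p = 0.48), and 3 members were higher.

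Markers of other marrow cells differed between the groups as well. Basophil and mast cell genes were higher in MOP: of 19 genes on the basophil, mast cell and eosinophil list 10 were higher, 1 was lower and 8 did not pass. Il4, a cytokine of these cells, had a log2 fold change of 3.62 ± 0.56 (SE) and Cyp11a1, a steroid synthesis enzyme, of 3.59 ± 0.41. Il4 rests on few reads, with 1, 6 and 1 counts in MODP replicates 1 to 3 and 43, 41 and 35 in MOP. Prss34 and Mcpt8, proteases of basophils, stood at 278 ± 196 and 138 ± 79.1 CPM in MODP and at 2379 ± 567 and 923 ± 210 CPM in MOP. The eosinophil granule genes Prg2 and Epx did not pass the test (edgeR adjusted p = 0.89 and 0.66). The lower member was Siglecf, an eosinophil lectin, which fell by 0.64 ± 0.11 (SE) on the log2 scale. By camera, the adjusted p was 1.1e-05, and adjusted p = 0.45 with an estimated correlation. With the replicate number as a block 5 members were higher and 2 lower, as 2 were with the title number, Prss34 and Mcpt8 lost their calls (edgeR adjusted p = 0.093 and 0.083), and without MODP replicate 1, MOP replicate 1 or MOP replicate 3 the higher members were 6. Replicate 2 was the highest MODP library and the lowest MOP library for all 10 higher members.

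Genes of erythroid cells and megakaryocytes were mostly higher in MOP and those of T and NK cells lower. On the erythroid and megakaryocyte list 12 of 23 genes were higher, 1 was lower and 10 did not pass, with 12 higher and 2 lower adjusted over the list alone. The erythroid factor genes Klf1 and Gata1 rose from 10.9 ± 2.33 to 29.9 ± 5.62 CPM and from 11.6 ± 2.74 to 31.7 ± 6.46 CPM. Camera gave an adjusted p of 0.00071, and adjusted p = 0.55 with an estimated correlation. On the T and NK list 14 of 21 genes were lower, 0 were higher and 7 did not pass, with 16 lower adjusted over the list alone. Nkg7, a granule protein gene of NK and T cells, fell from 227 ± 20.2 to 85.5 ± 18.1 CPM, Lck, a T cell kinase gene, from 10.8 ± 5.64 to 1.64 ± 0.464 CPM, and Tcf7, a T cell transcription factor gene, from 7.84 ± 1.77 to 1.72 ± 0.929 CPM. The camera adjusted p was 1.0e-08, and adjusted p = 0.48 with an estimated correlation. The higher erythroid and megakaryocyte members were 7 without MODP replicate 1 or without MOP replicate 1, and 2 or 3 were lower in 10 of the 17 alternatives. For 19 of the 23 erythroid and megakaryocyte members, among them Klf1 and Gata1, replicate 2 was the highest library of both groups. The same held for 18 of 21 B lineage, 17 of 21 T and NK, 18 of 24 granulocyte and 21 of 29 interferon members. It also held for 9 of 15 stromal and endothelial members, against 19.1% of the 12850 tested genes. The lower T and NK members were 8 without MOP replicate 1 or without MOP replicate 3. Of the 14 lower members, replicate 2 was the highest library of MODP for 13 and of MOP for 12.

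None of the 21 B lineage genes passed edgeR's test, where 3 (Rag2, Ighm and Jchain) had an unadjusted p under 0.05; Ighm, an immunoglobulin heavy chain gene, averaged 336 ± 22.2 CPM in MODP and 766 ± 352 CPM in MOP (edgeR adjusted p = 0.062). Ighm was called higher with DESeq2 (adjusted p = 0.0091) and limma-voom (adjusted p = 0.020). With edgeR it was called without robust estimation, with the title number as a block, without MOP replicate 2 or 3 and without both replicate 2 libraries (adjusted p = 0.018, 0.034, 0.0020, 0.041 and 0.00059). DESeq2 called 2 of the B lineage genes higher, as did edgeR without robust estimation, and limma-voom called 1 higher and 1 lower. With the replicate number as a block 5 were lower, with the title number 1 was higher and 4 lower, and without both replicate 2 libraries 1 was higher and 3 lower. Camera did not call the B lineage list (adjusted p = 0.39), except without MODP replicate 3 (adjusted p = 0.031). On the stromal and endothelial list 3 of 15 genes were lower in MOP, 0 were higher and 12 did not pass. Pdgfrb, a growth factor receptor gene, fell from 24.2 ± 1.54 to 5.92 ± 1.24 CPM, and Flt1, a VEGF receptor gene, from 11.0 ± 1.28 to 4.92 ± 1.69 CPM. The other lower member was Runx2, which is also on the plasmacytoid dendritic cell list. The collagen gene Col1a1 did not pass the test (edgeR adjusted p = 0.48): it stood at 1727 CPM in MODP replicate 2 and 192 CPM in MOP replicate 2, and at 0.493 to 49.2 CPM in the other libraries. The lower members had no such peak in MODP replicate 2. Across the MODP libraries Pdgfrb was at 22.5 to 25.5, Flt1 at 9.56 to 11.9 and Runx2 at 77.2 to 94.4 CPM. By camera, the adjusted p was 0.023 for the stromal and endothelial list, and adjusted p = 0.54 with an estimated correlation. That call was also lost under upper-quartile scaling, without a filter, and without MOP replicate 1, MODP replicate 2 or MOP replicate 3 (adjusted p = 0.053, 0.081, 0.071, 0.17 and 0.14), and 5 members were lower without MOP replicate 2, without both replicate 2 libraries and with the replicate number as a block. With that block, with DESeq2, without robust estimation and without MOP replicate 3, 1 member was higher.

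**Figure D3:**
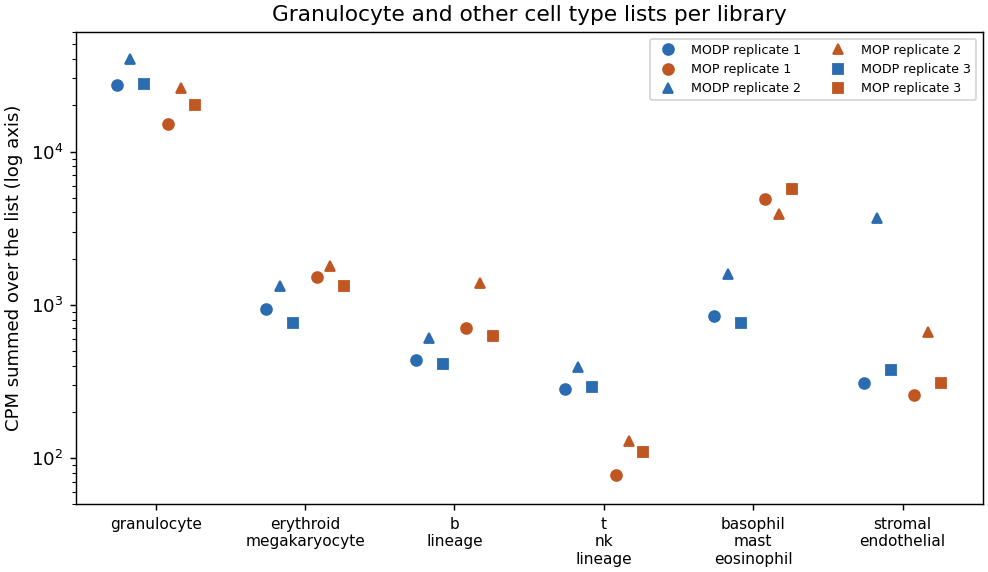
CPM summed over the members of the granulocyte list and of 5 lists of other cell types, on a log axis, with colour for the group and marker shape for the replicate number. The basophil, mast cell and eosinophil sum is 760.4 to 1582 in MODP and 3934 to 5699.8 in MOP, and the stromal and endothelial sum reaches 3706 in MODP replicate 2.

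Cell cycle genes were modestly higher in MOP. On the S phase list 15 of 30 genes were higher and 0 were lower, and on the G2 and M phase list the same numbers; adjusted over the list alone, 18 and 17 were higher. Ccne1, which encodes cyclin E1, rose from 29.8 ± 3.29 to 57.8 ± 3.17 CPM, Rrm2, a subunit of ribonucleotide reductase, by log2 0.49 ± 0.05 (SE), and Mki67, a proliferation marker, by 0.62 ± 0.05. Racgap1, which acts in cytokinesis, rose by 0.59 ± 0.07. The median log2 fold changes were 0.19 and 0.20. Camera gave adjusted p values of 0.00045 and 0.0020, and adjusted p = 0.54 for both with an estimated correlation. Without MOP replicate 1, 6 S phase genes were higher, and the G2 and M phase count was 8, 9 or 8 without MODP replicate 1, MOP replicate 1 or MOP replicate 3.

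Ribosomal protein genes were slightly lower in MOP. Of 34 genes 23 were lower, 0 were higher and 11 did not pass, with 26 lower adjusted over the list alone and a median log2 fold change of -0.23. Rps20 fell by 0.31 ± 0.05 (SE) on the log2 scale, and Rps4x fell by 0.30 ± 0.05 but shares 77.8% of its 31-mers with other genes. Camera gave an adjusted p of 0.00019, and adjusted p = 0.39 with an estimated correlation. The count of lower members was 11, 7, 9 and 13 without MODP replicate 1, MOP replicate 1, MOP replicate 2 and MODP replicate 3.

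Genes of energy metabolism moved little. On the oxidative phosphorylation list 3 of 31 genes were lower and 0 were higher: Ndufa4, Ndufb5 and Cox6c, subunits of the respiratory chain, fell by 0.31, 0.32 and 0.21 on the log2 scale, and 2 of them passed when adjusted over the list alone. Of 19 glycolysis genes 4 were lower and 2 were higher, or 6 and 2 adjusted over the list alone. Pfkfb3, a regulator of glycolysis, fell by 0.51 ± 0.07 (SE) on the log2 scale, the enzyme genes Pfkl and Gpi1 by 0.40 and 0.29, and Tpi1 by 0.26; the kinase genes Hk2 and Pfkp were higher, both at log2 0.42. Camera called neither list (adjusted p = 0.30 and 0.62), and for glycolysis the median and mean were above 0, at 0.0082 and 0.013, while camera's direction was down. Under upper-quartile scaling 5 oxidative phosphorylation genes and 7 glycolysis genes were lower, and with the replicate number as a block 4 glycolysis genes were higher. Cox6c lost its call in 4 of the 6 fits without a library, those without replicate 1 of MODP or any MOP library, and without both replicate 2 libraries (edgeR adjusted p = 0.059), and 2 oxidative phosphorylation genes were higher without MODP replicate 2.

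Immediate early and stress genes were called almost nowhere without the block: of 27 genes Egr2, an early response factor gene, was lower, 0 were higher, and 0 passed in either direction adjusted over the list alone. Egr2 averaged 6.49 ± 1.74 CPM in MODP and 3.39 ± 0.452 CPM in MOP (edgeR adjusted p = 0.021). Fos, an early response factor gene, did not pass the test without the block (edgeR adjusted p = 0.18). It was at 2408, 2339 and 1512 CPM in MODP replicates 1 to 3 and at 3825, 3196 and 2324 CPM in MOP. Fos was thus higher in MOP in each replicate pair. With the replicate number as a block 17 members were higher in MOP and 3 were lower, and the camera adjusted p went from 0.32 to 0.0066. Egr2 lost its call without MODP replicate 1 and without each MOP library in turn (edgeR adjusted p 0.010 to 0.076 over the 6 fits) and without both replicate 2 libraries (edgeR adjusted p = 0.066), 2 members were higher with DESeq2, with limma-voom and without robust estimation, and camera called the list without MOP replicate 3 (adjusted p = 0.012).

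Interferon response genes went both ways. Of 29 genes 5 were higher, 3 were lower and 21 did not pass; adjusted over the list alone, 4 were higher and 2 were lower. The factor genes Irf9 and Stat2 and the antiviral genes Trim30a, Mx1 and Ifitm3 were higher, with Irf9 at log2 0.59 ± 0.07 (SE) and Mx1 at 1.52, whereas Ifi47 fell by 0.84 ± 0.12, Bst2 by 0.30 and Igtp by 0.37. Camera did not call the list (adjusted p = 0.51). With the replicate number as a block 10 were higher and 6 lower, 10 were higher with the title number, 11 were higher without MODP replicate 2, 10 were higher without replicate 2 of both groups, and 1 was lower without MOP replicate 1.

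**Figure D4:**
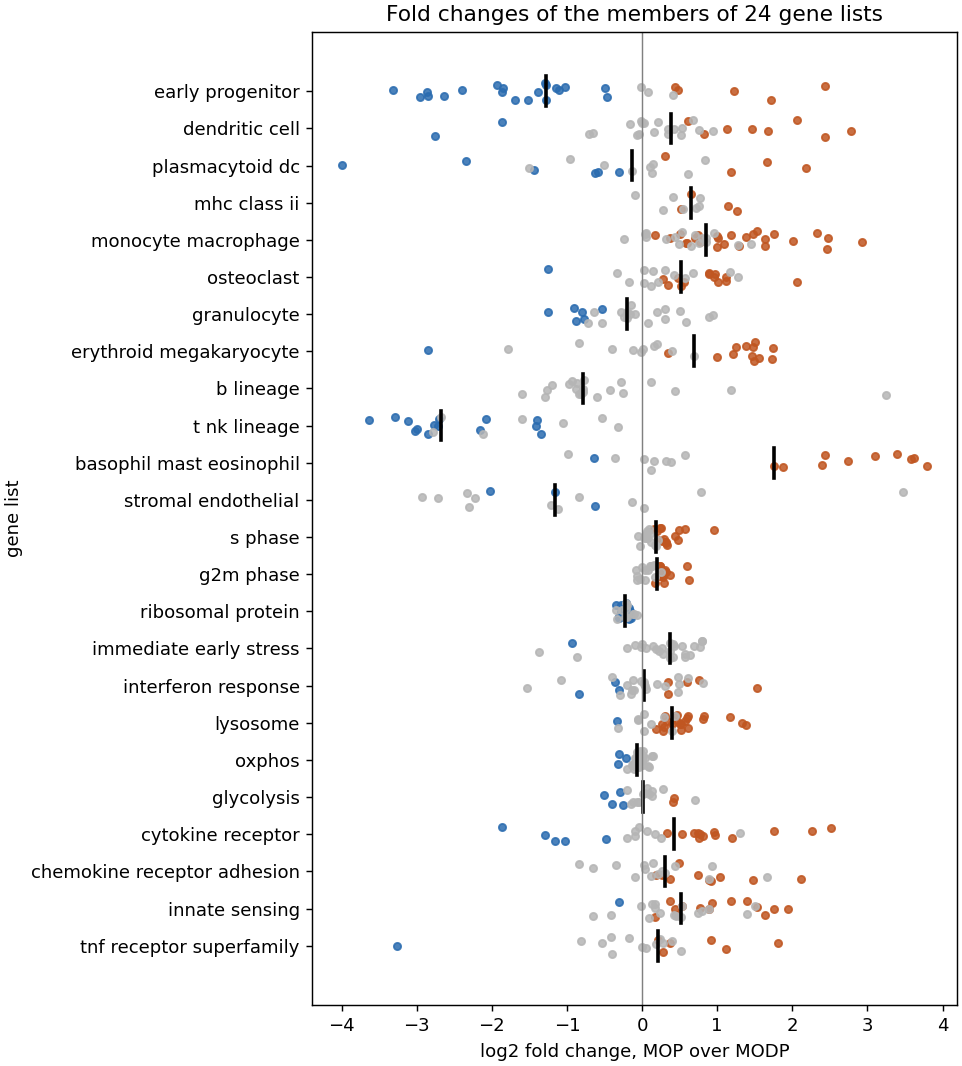
Log2 fold change, MOP over MODP, of each tested member of the 24 gene lists; orange points passed the test as higher in MOP, blue as lower, grey did not pass, and black bars are list medians. The early progenitor median is -1.28, that of the T and NK list -2.67, that of the monocyte and macrophage list 0.85 and that of the basophil, mast cell and eosinophil list 1.76.

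Among genes with a symbol that averaged at least 10 CPM in a group, the largest rises were led by Ighv7-3, Alox8 and C3ar1. C3ar1, the receptor for complement C3a, rose from 0.457 ± 0.321 to 10.3 ± 3.71 CPM, Cd200r3, an activating receptor of basophils and mast cells, from 5.58 ± 3.24 to 113 ± 33.3 CPM, and Il6, the cytokine gene, from 0.995 ± 0.513 to 14.7 ± 3.00 CPM. Alox8 and Alox15, lipoxygenase genes, had log2 fold changes of 4.64 ± 0.78 and 3.80 ± 0.73 (SE), the glutamate receptor gene Grm6 of 4.11 ± 0.53 and the laminin gene Lama5 of 3.82 ± 0.36. Alox15 is also on the basophil, mast cell and eosinophil list. For every higher member of that list replicate 2 was the highest MODP and the lowest MOP library. The same held for Alox8, Grm6, Lama5 and Cd200r3, but not for C3ar1, Il6 or Ighv7-3. Ighv7-3, an immunoglobulin variable segment, had 3 counts over the MODP libraries and 1669 over the MOP libraries, at 346, 1240 and 83 in replicates 1 to 3. The ratio of MOP to MODP, scaled by library size, was 486 (exact binomial 95% interval 166 to 2359, counting error only). Alox15 lost its call with the replicate number as a block (edgeR adjusted p = 0.089) and in 4 of the 6 fits without a library, those without MODP replicate 1 or any MOP library (0.011 to 0.086 over the 6). Ighv7-3 lost its call without MOP replicate 1 and without each MODP library in turn (edgeR adjusted p 0.011 to 0.13 over the 6 fits), and also with limma-voom, without a filter on low counts and without both replicate 2 libraries (adjusted p = 0.12, 0.058 and 0.064).

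The largest falls among such genes were led by Dntt, Ctla2a and Kcng1. Dntt had a log2 fold change of -4.00 ± 0.50 (SE; edgeR adjusted p = 0.0043), Ctla2a, a protease inhibitor gene, of -3.55 ± 0.27, and Kcng1, a potassium channel gene, of -3.29 ± 0.16 (edgeR adjusted p = 4.3e-05), and Cd27 and Hoxa9 stood at -3.27 and -2.96. The T and NK cell genes Il2rb, Ccl5 and Lck stood at 16.5 ± 8.68, 11.9 ± 8.38 and 10.8 ± 5.64 CPM in MODP and at 2.00 ± 2.04, 1.61 ± 0.711 and 1.64 ± 0.464 CPM in MOP. Il2rb lost its call in 5 of the 6 fits without a library (edgeR adjusted p 0.013 to 0.14), all but that without MOP replicate 2, and also without a filter on low counts (adjusted p = 0.12). Ccl5 lost its call without MODP replicate 1 and without each MOP library in turn (edgeR adjusted p 0.0025 to 0.12 over the 6 fits). Further losses for Ccl5 came with limma-voom, without a filter on low counts and without both replicate 2 libraries (adjusted p = 0.076, 0.11 and 0.057).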

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

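The fit with the replicate numbers of the columns as a block and the fit without both replicate 2 libraries were chosen after the data had been seen; the other alternatives were fixed before. None of the 82 genes named by rule turned its direction in any alternative, and 72 of the 80 that were called stayed past the threshold in each of the 6 fits without a library. Tested against a 1.5-fold change, 510 genes passed, 295 higher and 215 lower in MOP, and the higher members became 4 of the dendritic, 10 of the monocyte and macrophage and 4 of the osteoclast list, because that test asks for a larger change. Without 1 library at a time, 2317 to 4799 genes passed, 1281 to 2524 of them higher and 1036 to 2275 lower. With an estimated correlation the camera adjusted p was 0.52 for the dendritic, 0.34 for the monocyte and macrophage and 0.34 for the osteoclast list, and 16 of the 17 camera calls were lost; fry's directional test called 13 of the 17 and its mixed test all 17 of them and 5 other lists. With the replicate number of the columns as a block 5268 genes passed, 3986 of them shared with the 4008, and 0 changed direction; 33 of 48 list counts stayed within 1.5 times, higher basophil members went from 10 to 5, and of the genes in the text Alox15, Gata2, Mcpt8 and Prss34 lost their calls. With the title number as a block 4826 passed, and without both replicate 2 libraries 4362 (3488 shared). The other settings gave 3785 (DESeq2) to 4144 (upper-quartile scaling) genes, and 43 to 48 of the 48 list counts stayed within 1.5 times. Their cause was not tested where a list count moved further. At this depth and with 3 libraries a group, changes of 1.5-fold were recovered in 43.8% of simulated cases. The adjustment was less strict with 4008 real calls than with 163 simulated ones, so this share does not describe the real comparison. Genes that did not pass are still not shown to be unchanged.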

Other observations

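The tests of shared reads, of a lower share of progenitors and of sequencing depth were chosen after the results they bear on had been seen, and the other tests before. The test of shared reads replaced an earlier form that had picked genes by their outcome. The 4 extra marker lists were written before their values were examined. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 4008 genes, and the highest of the others gave 0. Among those others, 3 parted all 3 replicate pairs as the real split does, each leaving 1 pair turned round. With 10 splits the share cannot fall under 0.1, which is too few for such a test.

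Genes of basophils and mast cells were higher in every MOP library than in any MODP library as a sum, although the sort was for progenitors. Of 15 tested genes on a further basophil list, 12 were higher in MOP and 1 (Rab44) was lower, which is consistent with basophil-lineage cells in the MOP libraries. Among the most abundant of them were Ccl3, at 377 to 539 CPM in MOP and 62.3 to 105 CPM in MODP, and Csf1, at 113 to 186 CPM and 11.9 to 21.4 CPM; macrophage-lineage cells can express both. Reads shared with near-identical copies are argued against, since the 10 members higher in MOP shared at most 4.86% of their 31-mers with other genes. Expression of these genes by the MOP progenitors themselves stays open and was not tested.

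T and NK cell genes were lower in MOP. Of 17 tested genes on a further T and NK list, 7 were lower and 2 were higher, so T and NK cells in the MODP libraries cannot be told apart from other explanations; the 7 fall short of the 9 that were asked for beforehand. The test of a lower share of progenitors in the MODP libraries assumed that other cell types rise there alike, which is not known. The 14 extra late neutrophil genes had a median log2 fold change of 0.33 (quartiles -0.17 and 0.63), with 2 higher and 0 lower. The median was -2.67 for the T and NK list and -0.72 (quartiles -2.21 and 0.35) for the further T and NK list. Stromal and endothelial, B lineage and granulocyte medians were -1.16, -0.79 and -0.20. Erythroid and megakaryocyte and basophil list medians were 0.69 and 1.76. Lists of other cells thus went both ways, and the progenitors may express some members too, so the test does not decide this explanation. Of the 14 members of the T and NK list lower in MOP, replicate 2 was the highest library of MODP for 13 and of MOP for 12. A difference between the progenitors themselves stays open and untested.

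The replicate 2 libraries of both groups stood apart on the second principal component. Of 21 tested genes on the late neutrophil and osteoblast lists, 16 (76.2%) were highest in replicate 2 of both groups, against 19.1% of the 12850 tested genes, which is consistent with RNA of other marrow cells in these libraries. The 16 were 12 of 14 late neutrophil genes and 4 of 7 osteoblast genes. The osteoblast genes Fbn1, Omd and Timp3, which are among them, were at most 2.37 CPM in any library. Anxa1 stood at 292, 702 and 265 CPM in MODP replicates 1 to 3 and at 419.8, 655 and 488 CPM in MOP. Hp was highest in replicate 2 of MODP and not of MOP, and 0 of the 7 osteoblast genes passed the comparison of MOP with MODP. Sequencing depth is argued against for the 21 genes, since replicate 2 was the shallowest MODP and the deepest MOP library. Their median log2 ratio to the other libraries was 1.33 in MODP and 0.97 in MOP. Most of them had already been seen highest in replicate 2 of both groups, so the ratio is not a separate test. A biological difference between the replicate pairs was not tested.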
